A study of Caenorhabditis elegans with 5 samples.

How the data were processed

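ALR-1 is a homeodomain transcription factor of the nematode Caenorhabditis elegans, of the aristaless family, known from work on sensory and motor neurons. Per the labels, the worms were of strain OP200, which carries an integrated transgene coding for ALR-1 fused to EGFP and FLAG tags, together with a rescuing copy of unc-119, a gene expressed in neurons. Hermaphrodites were grown at 20 °C to the L2 larval stage and fixed with 2% formaldehyde. Per the labels' protocols, chromatin was sheared by sonication, 10% of the extract was kept as input DNA, and the rest was precipitated with a goat antibody against GFP. Whole animals were used, so each library mixes all tissues. The series holds 5 sequencing libraries. The labels put 3 of them in the ChIP group, 2 with the replicate number 1 and 1 with the replicate number 2. The other 2 are input DNA, and both carry the replicate number 1 in their titles. The labels do not say whether the replicates came from separate cultures.

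The deposited data were 3 peak lists, named for replicate 1, replicate 2 and the combination of the replicates. Peaks were called with PeakSeq on the WormBase WS190 genome build, per the file headers and the source column of the files. PeakSeq scores windows with more ChIP reads than a scaled background and adjusts the scores for multiple testing. The only value deposited with each peak was the q-value the authors' peak caller gave it, and it stood identically in 2 fields of each line. Every q-value was below 0.01. The PeakSeq version, the aligner, the input used for each list and the way in which the replicates were combined are not given in the sources used here. Neighbouring peaks of a list were never closer than 200 bp. No read count, fold enrichment or library total was used here, so the depth behind each peak is unknown, and the strength of a peak is stated as −log10 of the authors' q-value. A q-value depends on read depth as well as on enrichment, so it was used to rank and filter peaks within a list. Strengths of different lists that are set side by side, as medians or at named peaks, describe the lists and do not measure a change in binding. Tests that join lists took strengths at the same position and compared them across peaks or between chromosomes of the same lists.

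The gene table at hand is on the assembly WBcel235, not WS190, and no genome sequence was used here. Coordinates were not transferred between builds, so peaks are named by WS190 position (counted from 1) and no peak is assigned to a gene. The promoter test, the test of 22 tissue and gene family lists and the test of a homeodomain core sequence, all planned before the data were examined for the case that a matching build was at hand, were not run. Chromosome lengths of WS190 were not used either. The stretch from the start of the first peak to the end of the last peak of any list stood for the length of each chromosome, which departs from the plan to run the density test on known lengths.

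Overlap meant at least 1 bp shared. Overlap between the replicate lists was tested with a circular-shift permutation test: the replicate 2 peaks of each chromosome were moved together by a random offset, wrapping at the ends, 10000 times, with a two-sided p. The smallest p this test can give is 0.0001. Shares carry Wilson 95% intervals, which cover counting error only, and a share of 0 also carries the limit set by 3 counts. The relation of strengths between lists was computed across peaks with 100000 permutations, and peaks are not independent replicates. The density on X was compared with that on the autosomes by a two-sided exact binomial test. Bootstrap intervals used 2000 draws of peaks. With 2 replicate lists, no SD over replicates is given and both values are printed. The lists were read and tested with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots were drawn with matplotlib 3.10.9.

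The shift test was tested on simulated data. In 100 pairs of unrelated simulated lists of about the sizes of the replicate lists, 6 gave a p below 0.05. The simulated peaks were placed uniformly at random along each chromosome, and fewer shifts were used than on the data. Real peaks cluster and crowd the middle of the autosomes, so the error rate under such crowding was not tested. The planted shared peaks were exact copies, so finding 300 of 300 checked the overlap count only. The alternatives planned before the data were examined were a stricter threshold (the stronger 50% of a list), a reciprocal overlap of 50%, midpoints within 200 bp, lists of equal length, peaks within 1 kb merged, and each replicate list alone. Alternatives without chromosome I, and the stronger 50% of each replicate list for the X comparison, were added after the data were seen. The peaks named below follow a rule fixed before the data were examined: the 15 combined peaks with the smallest q-values that overlapped both replicate lists, and the strongest peak of each replicate list that overlapped no peak of the other. Further peaks are named as chosen after their values were seen.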

Results

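Binding of ALR-1-GFP in L2 larvae was mapped by chromatin immunoprecipitation and sequencing against input DNA, and the series asked where in the genome the tagged factor was found. The ChIP group had 3 libraries and the input group 2. The comparison of ChIP with input was made by the authors when they called peaks, and its outcome was 3 lists. The combined list held 6159 peaks that covered 2927 kb, or 2.93% of the stretch of the genome between the outermost peaks. The replicate 1 list held 1628 peaks over 834 kb and the replicate 2 list 3994 peaks over 1821 kb. Most peaks were narrow in every list. The median width was 372 bp in the combined list (interquartile range 273 to 538 bp), 374 bp in replicate 1 and 369.5 bp in replicate 2. A few peaks were long, and 90 combined peaks exceeded 2000 bp. The median strength, as −log10 of the authors' q-value, was 2.95 in replicate 1, 3.76 in replicate 2 and 4.06 in the combined list. Total read counts of the libraries were not used here, so the depth behind the difference in list length is unknown. The comparisons by strength class, of overlap by chromosome, of peak width, of the combined list on chromosome I, and of X without chromosome I or in the stronger 50% of each replicate list were chosen after the data were seen.

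The strongest signal lay on chromosome X in a region of 14.89 kb, from 11123547 to 11138436. It held 4 combined peaks separated by less than 1 kb each, of which 3 ranked 1, 2 and 4 among all combined peaks. The strongest, at 11134579 to 11138436, had a strength of 219.0, and its neighbour at 11129688 to 11134334 had 123.0. The combined peaks covered 91.8% of the region. Replicate 1 had 8 peaks there that covered 72.9% of it, the strongest with 36.1, and replicate 2 had 6 peaks that covered 83.0%, the strongest with 85.2. The first 4 ranks of the replicate 2 list all fell in this region, whereas in replicate 1 the best rank there was 5. The transgene carries alr-1, which is an X-linked gene, but whether this region contains it was not determined, because the gene table at hand is on another build.

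**Figure D1:**
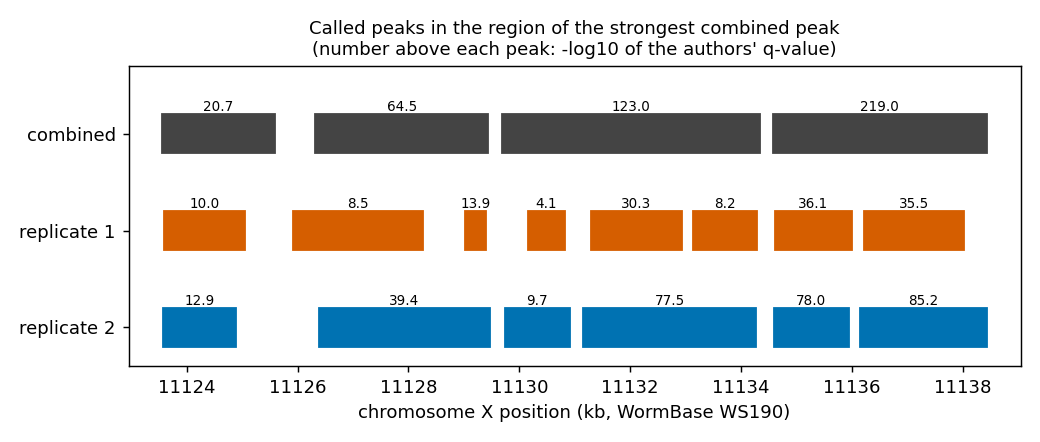
Peaks called on chromosome X (horizontal axis, WS190 position in kb) around the strongest combined peak, 1 row per list, with the −log10 q-value printed above each peak. Peaks of all 3 lists tile most of the 14.89 kb, with the largest values at the right-hand end.

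Of the 15 strongest combined peaks that overlapped both replicate lists, 7 lay on chromosome I, 6 on X, 1 on II and 1 on III, and none lay on IV or V. Besides 3 peaks of the region above, the X peaks were at 16929321 to 16931993 (strength 57.8), 2996511 to 2997476 (40.6) and 12689503 to 12690753 (38.4). The 7 peaks on chromosome I were at 7656645 to 7660500 (80.4), 3822335 to 3825276 (41.7), 9721737 to 9722722 (40.9), 7370045 to 7370558 (39.0), 9372732 to 9373817 (37.9), 9787581 to 9788928 (36.5) and 10031615 to 10033232 (36.2). The peak on III was at 3969054 to 3969802 (38.4) and that on II at 512017 to 513036 (38.02). The replicate 2 peak had the higher strength at 13 of the 15 positions. Replicate 2 values were higher in general: over the 1232 replicate 1 peaks with a single replicate 2 partner, the median was 3.10 in replicate 1 and 6.00 in replicate 2. The 2 exceptions were at 16929321 to 16931993 on X, where the strongest replicate 1 peak had 59.6 and the strongest replicate 2 peak 3.54, and at 7656645 to 7660500 on I, with 46.1 and 6.75. The number on chromosome I depended on the list used for ranking: ranked instead by the summed strength of the replicate peaks, a choice made after the data were seen, 2 of the top 15 lay on I, 6 on X, 3 on II, 2 on III and 2 on IV, and 9 peaks were in both rankings.

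The replicate lists were compared to ask how far the binding regions recurred. Of the 1628 replicate 1 peaks, 1239 overlapped a replicate 2 peak, which is 76.1% (Wilson 95% interval 73.97 to 78.1%). Of the 3994 replicate 2 peaks, 1240 overlapped a replicate 1 peak, which is 31.05% (29.6 to 32.5%). Circular shifts gave 3.89% and 1.60% on average, and at most 18.2% and 7.51%, so the observed overlap was 19.6-fold and 19.4-fold that of shifted lists (permutation p = 0.0001 for each share, the smallest that 10000 shifts can give). By chromosome, the overlapped share of replicate 1 peaks ran from 73.05% on V (67.3 to 78.1%) to 80.8% on III (75.4 to 85.3%). That of replicate 2 peaks ran from 26.3% on II (22.99 to 29.8%) to 35.9% on I (32.3 to 39.7%). When replicate 2 was reduced to its 1628 strongest peaks, 50.9% of replicate 1 peaks were overlapped. The labels do not say whether both lists were called against the same input, and a shift test does not separate shared binding from shared background.

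Overlap rose with strength from the weakest to the strongest 10% of each list. In the strongest 10% of the replicate 1 list 92.0% of peaks were overlapped (86.8 to 95.3%, 163 peaks), against 59.9% in the weakest 10% (52.2 to 67.1%, 162 peaks). The rise did not continue to the very top of replicate 1. Of the 13 peaks without a partner in its strongest 10%, 7 ranked within the first 19 of the list. In replicate 2 the strongest 10% reached 77.2% (72.9 to 81.1%, 400 peaks) and the weakest 12.5% (9.64 to 16.1%, 399 peaks). Across 1232 replicate 1 peaks with a single replicate 2 partner, strengths were related with Spearman's rho of 0.39 and Pearson's r of 0.55 (permutation p = 1e-05 for each, the smallest possible, 2 coefficients computed on the same peaks). Without the 2 peaks farthest from the median replicate 1 strength, both in the 14.89 kb region on X, r was 0.42 and rho 0.39. The strongest replicate 1 peak among the 1232 had 36.1. The single-partner rule thus left out the replicate 1 peaks of 59.6 on X and 46.1 on I, whose strongest replicate 2 peaks had only 3.54 and 6.75.

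**Figure D2:**
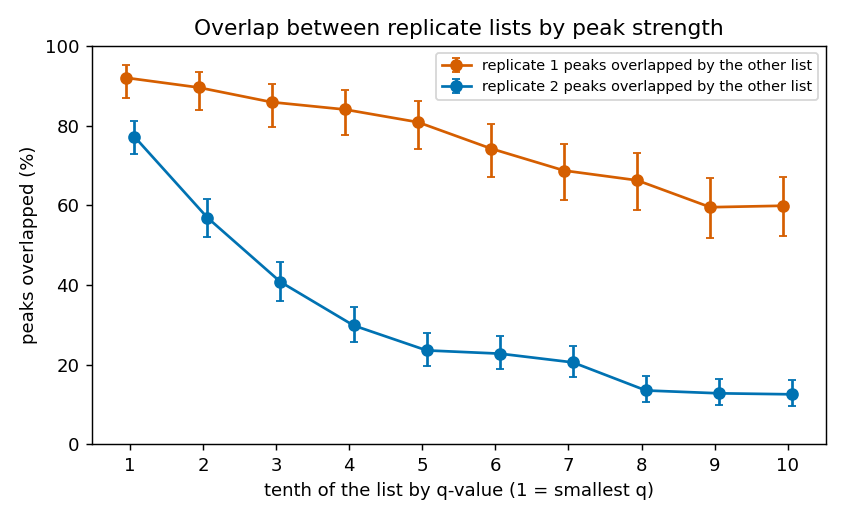
Percent of peaks of each replicate list overlapped by the other list (vertical axis) in 10 classes of near equal size ordered by q-value (horizontal axis, 1 is the strongest). Points are shares and bars Wilson 95% intervals, and the share falls from 92.0% to 59.9% in replicate 1 and from 77.2% to 12.5% in replicate 2.

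Some strong peaks were found in 1 replicate list alone. The strongest replicate 1 peak with no replicate 2 partner lay on V at 1804024 to 1806229. It ranked 2 in its list with a strength of 56.8, and the nearest replicate 2 peak was 26928 bp away. The strongest replicate 2 peak with no replicate 1 partner lay on III at 8416913 to 8418065, ranked 18 in its list with a strength of 23.4, and was 4514 bp from the nearest replicate 1 peak. Among the 163 peaks of the strongest 10% of replicate 1, 13 had no replicate 2 partner. These 13 had a median width of 1424 bp against 535 bp for the 150 with a partner (two-sided permutation test of the medians, p = 0.002). The 2 sets were not matched for strength, and all 5 of the 13 that exceeded 2000 bp ranked within the top 13 of the list.

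The combined list was then set against the replicate lists. Both replicate lists overlapped 1232 combined peaks, which is 20.0% (Wilson 95% interval 19.02 to 21.02%), replicate 2 alone overlapped 2532 (41.1%), replicate 1 alone 349 (5.67%), and 2046 peaks (33.2%, 32.1 to 34.4%) were in neither. In the stronger 50% of the combined list, 39.8% were in both and 4.55% in neither. Peaks seen in both replicates were the strongest, with a median of 10.6, against 4.60 for those in replicate 2 alone, 4.19 for those in replicate 1 alone and 2.61 for those in neither. Of the replicate peaks, 35 of replicate 1 (2.15%) and 205 of replicate 2 (5.13%) were not overlapped by any combined peak. Which reads went into the combined list is not given in the sources used here, so these shares and strengths are not offered as an independent check. If the combined list used the replicate reads, the order of the median strengths would be largely built in.

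The combined list differed from the replicate lists on chromosome I. It held 1243 peaks there, or 82.8 per Mb, the highest density of the 6 chromosomes, against 69.5 per Mb on X and 45.3 to 67.5 per Mb on II to V. In replicate 2, chromosome I had 42.5 peaks per Mb, below the 46.5 on III and 45.8 on X. In replicate 1 it had 20.0 per Mb, also the highest of the 6, with 19.5 on X and 12.3 to 17.9 on II to V. The ratio of combined strength to the sum of both replicate strengths, over positions with 1 peak in each list, had a median of 1.34 on I (bootstrap 95% interval 1.31 to 1.37, 221 peaks) and medians of 1.05 to 1.08 on the other 5 chromosomes. On chromosome I, 44.4% of combined peaks (552 of 1243) were in neither replicate list, against 30.4% (1494 of 4916) elsewhere (Fisher's exact test, two-sided, p = 3.3e-20). The other 5 chromosomes ran from 28.4% on IV to 32.2% on X. The test treats peaks as independent although peaks cluster, and 1 chromosome, picked after the data were seen, stands on one side. Without chromosome I the combined list held 4916 peaks.

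**Figure D3:**
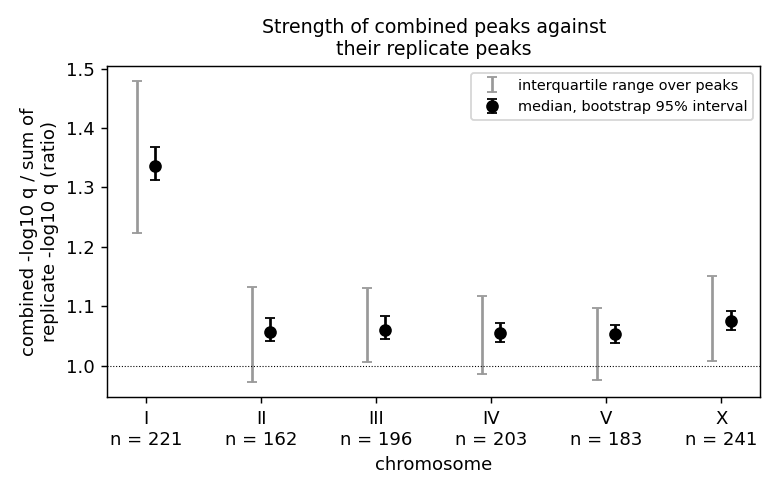
Combined −log10 q divided by the sum of the replicate 1 and replicate 2 −log10 q (vertical axis) for positions with 1 peak in each list, per chromosome (horizontal axis, n is the number of positions). Black points are medians with bootstrap 95% intervals and grey bars interquartile ranges, and chromosome I stands at 1.34 while the others lie between 1.05 and 1.08.

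Over the full length of the chromosomes, X carried more peaks per Mb than the autosomes together. The combined list had 69.5 peaks per Mb on X (1218 peaks) and 60.1 on the autosomes (4941 peaks), a ratio of 1.16 (exact 95% interval 1.09 to 1.23, exact binomial test, two-sided, p = 7.76e-06). The direction was the same in each replicate list, with a ratio of 1.24 in replicate 1 (1.10 to 1.402, p = 0.000487 by the exact binomial test) and 1.18 in replicate 2 (1.09 to 1.27, p = 4.18e-05 by the same exact test). Against II to V alone the combined ratio was 1.26 (1.18 to 1.35). In the stronger 50% of the combined list the ratio was 1.06 (0.969 to 1.16, exact binomial p = 0.193), and without chromosome I it was 1.21 in the stronger 50% (1.10 to 1.33). In the stronger 50% of the replicate 1 list it was 1.24 (1.04 to 1.47, exact binomial p = 0.0146), and in that of the replicate 2 list 1.02 (0.908 to 1.15, exact binomial p = 0.724). Peaks on X in replicate 2 had a median strength of 3.51, the lowest of the 6 chromosomes. The test treats peaks as independent, and peaks cluster. It also does not cover the spread among the autosomes. In each list 1 autosome was denser than X. This was I in the combined list (82.8 per Mb) and in replicate 1 (20.0 against 19.5 on X), and III in replicate 2 (46.5 against 45.8 on X). The excess on X was not found in the central 40% of the chromosomes, a division chosen after the data were seen. That part held 41.5% of combined peaks on X and 56.1% on the autosomes. Given the ratio above, X had fewer peaks per Mb there, with no separate test. The same held in replicate 1 (44.3% and 62.2%) and replicate 2 (40.5% and 56.2%).

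**Figure D4:**
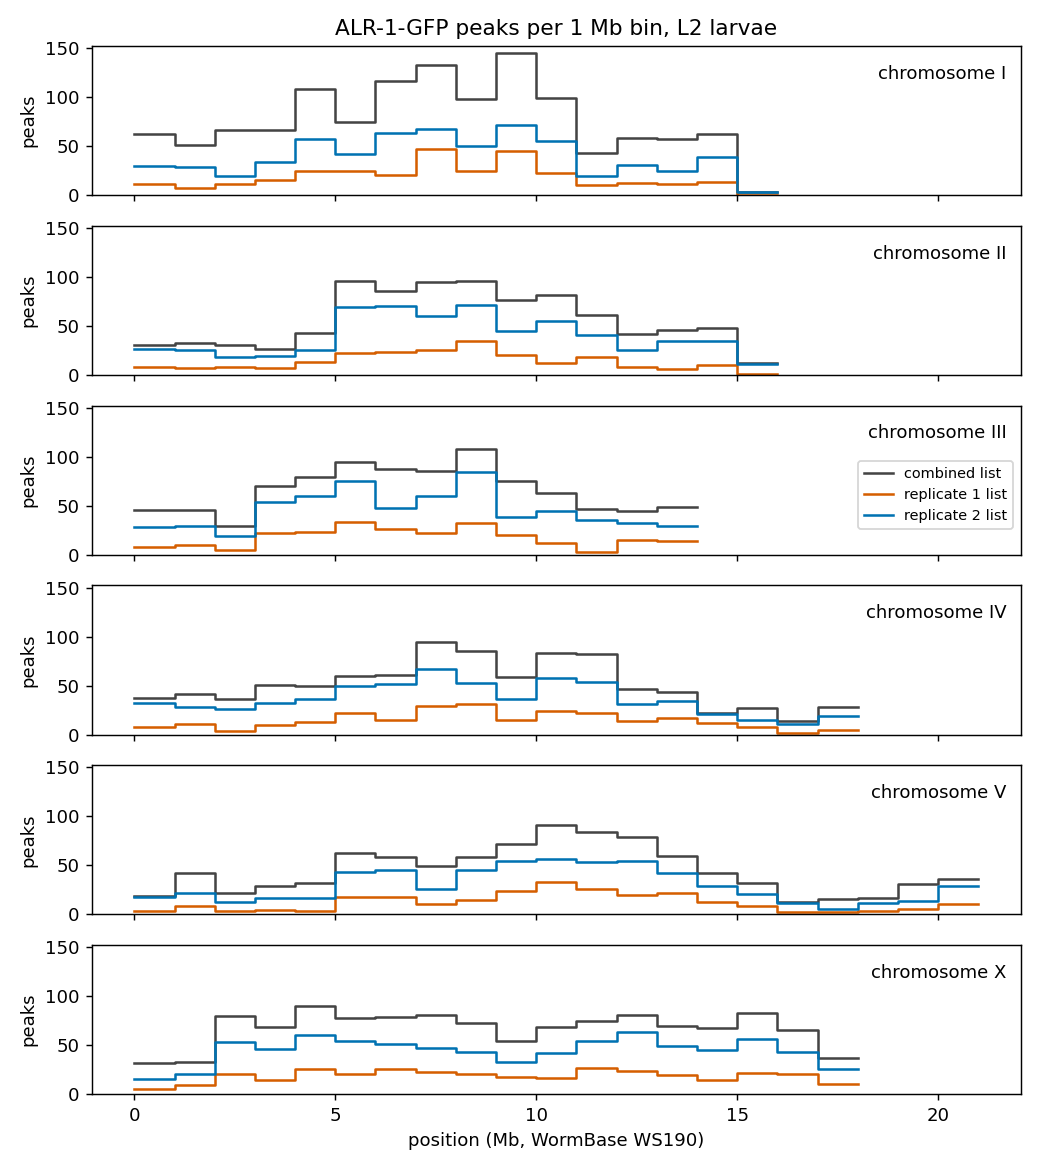
Peaks per 1 Mb bin (vertical axis) along each chromosome (horizontal axis, WS190 position in Mb) for the combined list and the replicate lists, with the last bin of each chromosome only partly filled. The combined list reaches 145 peaks between 9 and 10 Mb of chromosome I, whereas the highest bins of replicate 1 (47 peaks, I, 7 to 8 Mb) and replicate 2 (84 peaks, III, 8 to 9 Mb) lie elsewhere.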

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

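The tests without chromosome I, and those of X in the stronger 50% of each replicate list or of the list without chromosome I, were chosen after the data were seen. The overlap between replicate lists stayed above that of shifted lists, with permutation p = 0.0001, under all 5 alternatives, from 50.9% to 76.1% of replicate 1 peaks and from 28.0% to 50.7% of replicate 2 peaks. Spearman's rho of 0.39 became 0.42 with reciprocal overlap and 0.39 without chromosome I. The stronger 50% of each list held, by construction, 3080 combined, 814 replicate 1 and 1997 replicate 2 peaks, over 1807, 493 and 1049 kb. The share of combined peaks in both replicate lists was 17.6% with reciprocal overlap and 39.8% in the stronger 50%, and the share in neither was 35.8%, 4.55% and, without chromosome I, 30.4%. The X to autosome density ratio of 1.16 fell to 1.06 in the stronger 50% of the combined list, where p was no longer below 0.05 (exact binomial p = 0.193). Without chromosome I it was 1.26 in all peaks and 1.21 in the stronger 50%. It was 1.24 in the stronger 50% of replicate 1 (exact binomial p = 0.0146) and 1.02 in that of replicate 2 (exact binomial p = 0.724), and the cause of the lower ratios in the combined and replicate 2 lists was not tested. With 1 replicate list left out it ranged from 1.18 to 1.24, and it was 1.16 with peaks within 1 kb merged. The promoter, gene list and homeodomain core tests and their alternatives were not run. No paired analysis was possible because the peak lists hold no value per library and the input libraries carry 1 replicate number only. Without read counts, the depth that a missing peak would need cannot be stated, and an absent call is not absent binding.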

Other observations

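All tests in this part except the slopes on chromosome I and the near misses were chosen after the result was seen. Peaks on the autosomes were concentrated in the middle of the chromosome, and those on X were not. The central 40% of each autosome held 62.2% of replicate 1 peaks (Wilson 95% interval 59.6 to 64.8%), 56.2% of replicate 2 peaks (54.5 to 57.9%) and 56.1% of combined peaks (54.7 to 57.5%). On X the central 40% held 44.3% (39.1 to 49.6%), 40.5% (37.2 to 43.96%) and 41.5% (38.8 to 44.3%). Given the density ratios above, X had fewer peaks per Mb than the autosomes there in each list, although it had more over the full length. The autosomes differed from X in each list by Fisher's exact test (odds ratios of 2.07 with p = 3.6e-09, 1.88 with p = 1.9e-15 and 1.80 with p = 8.6e-20). These tests treat peaks as independent although peaks cluster, and only 1 chromosome stands on the X side. The combined list is not offered as an independent check of the replicate lists. In the combined list each autosome lay above 40%, from 52.6% on III to 59.6% on V.

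Some extremes were picked by rank, with no test against chance. The 100 kb window with the most replicate peaks, I from 7300001 to 7400000, held 10 replicate 1, 13 replicate 2 and 20 combined peaks. Next came, level in replicate peaks, II from 8500001 to 8600000 with 6, 16 and 19 and III from 8800001 to 8900000 with 5, 17 and 17. The longest stretch without a combined peak between neighbours was 276 kb on V, from 2324573 to 2600584, and neither replicate list had a peak inside it. The widest combined peak, X from 6736156 to 6745963, measured 9808 bp with a strength of 10.9 and overlapped 2 replicate 2 peaks and no replicate 1 peak. Very short peaks rarely recurred: of 12 replicate 1 peaks under 50 bp, 1 overlapped a replicate 2 peak, and of 38 such replicate 2 peaks, 0 overlapped a replicate 1 peak, which allows a share of up to 7.89% by 3 counts of the total and up to 9.18% by the Wilson interval, counting error only.

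Chromosome I stood apart in the combined list, where its peaks were more numerous and stronger than the replicate lists would give. More binding on chromosome I in the worms would raise the replicate lists too. The ratio of combined to summed replicate strength, 1.34 there against 1.05 to 1.08 on the other 5 chromosomes, restates the pattern and is no separate test. At the same positions, median strengths on I were 3.06 in replicate 1 and 5.97 in replicate 2. Both lay within the ranges elsewhere (3.04 to 3.18 and 5.46 to 6.56). The combined median was 13.1 on I against 9.38 to 10.6. The replicate strengths thus argue against stronger binding at these shared positions as the whole cause. Each of these positions has a peak in every list, so the medians cannot show binding seen as extra peaks, and replicate 1 peaks were densest on I. Whether the combined call used more ChIP reads, or less background, on chromosome I than the replicate calls did stays open. On I, 0.784% of replicate 2 peaks (5 of 638) were missing from the combined list against 5.96% (200 of 3356) elsewhere (Fisher's exact test, p = 2.3e-10). That test treats peaks as independent, with 1 chromosome on one side. Peaks of replicate 2 alone gained a median of 2.71 in strength on I against 0.632 to 0.860 elsewhere. Both differences follow from the smaller q-values themselves and do not decide the question. An excess of replicate 1 reads alone would leave the replicate 2 slope as on the other chromosomes. In a joint fit of combined strength on both replicate strengths, the replicate 2 slope on I was 1.17 times theirs (bootstrap 95% interval 1.06 to 1.29). The replicate 1 slope was 1.58 times (1.15 to 2.21). With peaks limited to a strength of 20, the ratios were 1.17 for replicate 2 and 1.23 for replicate 1. The raised replicate 2 slope goes against that excess but does not exclude it. The replicate strengths are correlated, so 1 slope can take up part of the other. No read counts were used here to settle the cause, and ranks of the combined list across chromosomes carry the difference on chromosome I.

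Of the 13 strong replicate 1 peaks without a replicate 2 partner, 7 ranked within the top 19 of their list, at 1804024 on V, 1503785 and 16940092 on X, 9051188 on III, 5372465 and 9320057 on I and 9088622 on V (start positions). Near misses of the overlap rule do not account for most of them, since 2 of the 13 had a replicate 2 peak within 1 kb (exact 95% interval 1.92 to 45.4%). Whether replicate 2 was enriched there too, but below its own threshold, stays open. The combined peak was stronger than the replicate 1 peak in 5 of 13, against 146 of 150 with a partner (Fisher's exact test, p = 5.5e-08), but those 150 have a replicate 2 peak above the threshold by definition. Among the weaker replicate 1 peaks that also lacked a partner, it was stronger in 316 of 376 (Fisher's exact test against the 13, p = 0.00037). That goes against the explanation, but the 2 sets differ in strength as well, so it does not decide it. A replicate 2 partner did not always add strength either: at 16929321 to 16931993 on X, with a partner of 3.54, the combined peak had 57.8 and the replicate 1 peak 59.6. Width was not compared at equal strength. All 5 of the 13 that exceeded 2000 bp ranked within the top 13 of the list. Peaks with a partner were wide at such ranks too: those ranked 5, 7 and 9, all in the 14.89 kb region on X, measured 1399, 1809 and 1631 bp. The greater width of the 13 thus does not single out broad enrichment particular to the replicate 1 libraries, a hypothesis that was not tested. A difference between cultures, and the choice of input for each list, stay open as well.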
